A study of Mus musculus with 21 samples.

How the data were processed

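The samples are RNA-seq libraries of myeloid cells sorted from the adipose tissue of male C57BL/6 mice fed a high fat or a normal diet for 16 weeks. Per the labels the tissue was digested with collagenase, the cells were separated by flow cytometry, and RNA from a PicoPure kit was amplified and made into libraries with a NuGen Ovation kit. The 21 libraries form 7 groups of 3. MHCII-low macrophages, CD11c-negative macrophages (MHC class II positive) and monocyte-derived cells come from both diets, and CD11c-positive macrophages come from the high fat diet only. The labels do not say that the replicates of a group are separate animals, so every p-value here measures spread between these samples.

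The deposited values are counts of reads per gene for 54532 genes, made by the authors with bcl2fastq, Trim Galore 0.4.5, STAR 2.6.0a and featureCounts of Subread 1.4.6-p5 on GRCm38. The strand setting is not given in the sources used here, so reads of a gene that overlaps another cannot be told apart. Of the genes given by name, 88 are overlapped by a gene on the other strand and 6 by a coding gene on the same strand. The report remarks on this for a few genes only. It also holds for others, such as Hadha, Hpgds, Cd9, Nr1h3 and Il1a. Gene IDs were matched to the mouse GENCODE release M21, 53229 with their version and 54409 without it. Members of gene families with similar sequences, such as Cd209a, Cd209d, Cd209f, Ccl8 and the Klr and H2 genes, can share reads and are less certain than the other genes.

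Library totals ran from 11245851 to 35568948 counts, the lowest in lean monocyte-derived replicate 3 and the highest in obese MHCII-low replicate 1. Counting error at these totals covers sampling of reads only, and reads copied by PCR are not independent molecules. The correlation of log2 CPM between replicates was 0.904 to 0.942 in lean monocyte-derived cells and 0.972 to 0.990 in the other groups. The 1st and 2nd principal components held 39.7% and 26.4% of the variance.

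Genes were filtered with filterByExpr, which left 22935 for testing, and libraries were scaled by TMM. CPM are TMM-scaled count rates from the cpm function of edgeR, given as mean ± SD with n = 3 in each group, and log2 CPM has a prior count of 2. Summed levels of lists and of receptor genes in the report are CPM of the library total without TMM scaling. A quasi-likelihood model of edgeR with robust settings was fitted to the 7 group means, with 14 residual degrees of freedom and a common dispersion of 0.0502. The spread of a gene is estimated over all 7 groups together. Replicates of lean monocyte-derived cells agreed less than those of the other groups, so p-values and SEs of comparisons with them may be too small. Tests were 2-sided, and Benjamini-Hochberg adjustment was made over all tested genes of a comparison. A gene is called where its adjusted p is under 0.05. Each log2 fold change is given with a standard error (SE) that its F statistic implies.

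The comparisons, the gene lists and the rule for naming genes were set before the data were examined. Named genes are the largest called rises and falls with a mean of at least 10 CPM in the higher group, an official symbol and no overlap between the libraries of the groups. They also include called members of each list by smallest p, and fixed sort and lineage genes. The 26 lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Each was tested again with an estimated correlation, and with fry. Members were also adjusted over the list alone. For each list the numbers of called members are given beside the median log2 fold change. 3 receptor and enzyme families were put together after the results were seen.

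Titles number the replicates 1 to 3, while descriptions number the lean monocyte-derived and lean CD11c-negative libraries 1, 3 and 4. Deviations from the group mean over 10132 genes were compared between groups to see whether equal numbers mark samples of common origin. In obese libraries 18 of 18 pairs of equal number had r above 0.1 (0.128 to 0.732) and pairs of unequal number ran from -0.671 to 0.173. In lean libraries pairs of equal description number ran from 0.0612 to 0.518, and pairs of equal title number from -0.314 to 0.518. Pairs of unequal description number ran from -0.348 to 0.554, the highest above every lean pair of equal number. The lean numbers thus do not clearly mark a common origin. The 2 such pairs above 0.1 both joined lean MHCII-low replicate 2, of description number 2, to libraries of description number 4. Its r was 0.554 with lean CD11c-negative replicate 3 and 0.210 with lean monocyte-derived replicate 3. A block on the description number leaves that library alone in its block, so lean fits with either block may not follow common origin. Fits with a block on the title number were run for all comparisons, and fits with a block on the description number for those within a diet and for differences of diet effects. The main fit has no block, so its p-values, SEs and counts leave out the correlation of obese libraries of equal number. The description block called more genes in each comparison between obese populations, so a gene that did not pass there may pass with it.

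Before the data were examined these alternatives were chosen: DESeq2 Wald tests, DESeq2 size factors, no filter, only the compared groups, a block on the title or description number, leaving out each library in turn, and other splits of the libraries. Leaving out both lean monocyte-derived libraries 1 and 3 was chosen after seeing the data. Counts were also simulated with 1 dispersion per gene for all groups, and with genes and libraries independent of each other. For the diet in MHCII-low macrophages edgeR found 52.2% of 113 genes given a log2 change of 1 and 88.5% of 87 given 2. Of its calls 3.55% were false, against 11.6% with DESeq2. For the diet in monocyte-derived cells it found 58.4% and 88.5% with 8.33% false (DESeq2 15.2%), and for an interaction 34.5% and 73.6% with 4.63% false (DESeq2 17.7%). The cell cycle list, moved in each simulation, was found by camera in all 3, with 0, 0 and 1 other lists called. The simulations left out the wider spread of lean monocyte-derived libraries and the correlation between libraries of equal number or between genes. They therefore do not measure false calls that come from these. Calculations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.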

Results

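RNA was measured in myeloid cells sorted from adipose tissue of lean mice on the normal diet and obese mice on the high fat diet. Each of 7 groups held 3 libraries: MHCII-low macrophages, CD11c-negative macrophages and monocyte-derived cells from both diets, and CD11c-positive macrophages from obese mice. Total counts per library ran from 20783760 to 21530356 in lean and 30083259 to 35568948 in obese MHCII-low macrophages, and from 22398499 to 25914583 and 26648301 to 31056402 in CD11c-negative macrophages. They ran from 11245851 to 20058521 in lean and 20871699 to 25642197 in obese monocyte-derived cells, and from 30073052 to 31965501 in CD11c-positive macrophages. Reads on 1731 olfactory and vomeronasal receptor genes, which these cells are not known to express, summed to 720 ± 431 CPM in lean monocyte-derived cells and 25.1 ± 1.54 CPM in CD11c-positive macrophages. Lean monocyte-derived replicate 3 had 11245851 counts, of which 67.1% lay on protein-coding genes, against 73.7% in replicate 1 and 82.5% in replicate 2.

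**Figure D1:**
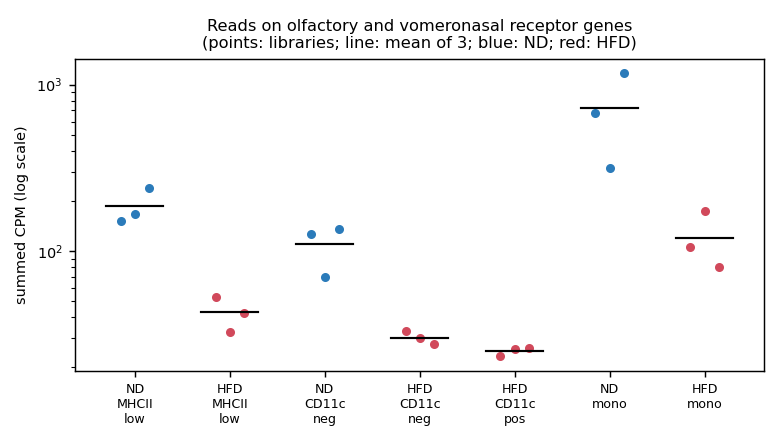
Summed CPM (log scale) of 1731 olfactory and vomeronasal receptor genes in each library by group, with points for libraries and a line at the mean of 3. Lean monocyte-derived libraries ran from 314 to 1172 CPM, and lean means lay above obese means in all 3 populations with both diets.

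The genes used for sorting were read as a check of the labels. H2-Ab1, a chain of MHC class II, stood at 346 ± 89.9 CPM in obese MHCII-low macrophages and at 2582 ± 331 CPM in obese CD11c-negative macrophages (SD, n = 3). Itgax, which encodes CD11c, stood at 85.0 ± 22.2 CPM in CD11c-negative and 587 ± 92.5 CPM in CD11c-positive macrophages. In monocyte-derived cells Itgax was 340.1 ± 32.4 CPM in obese and 319 ± 36.7 CPM in lean mice, and the dendritic cell receptor Ccr7 was 215 ± 104 and 243 ± 195 CPM.

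**Figure D2:**
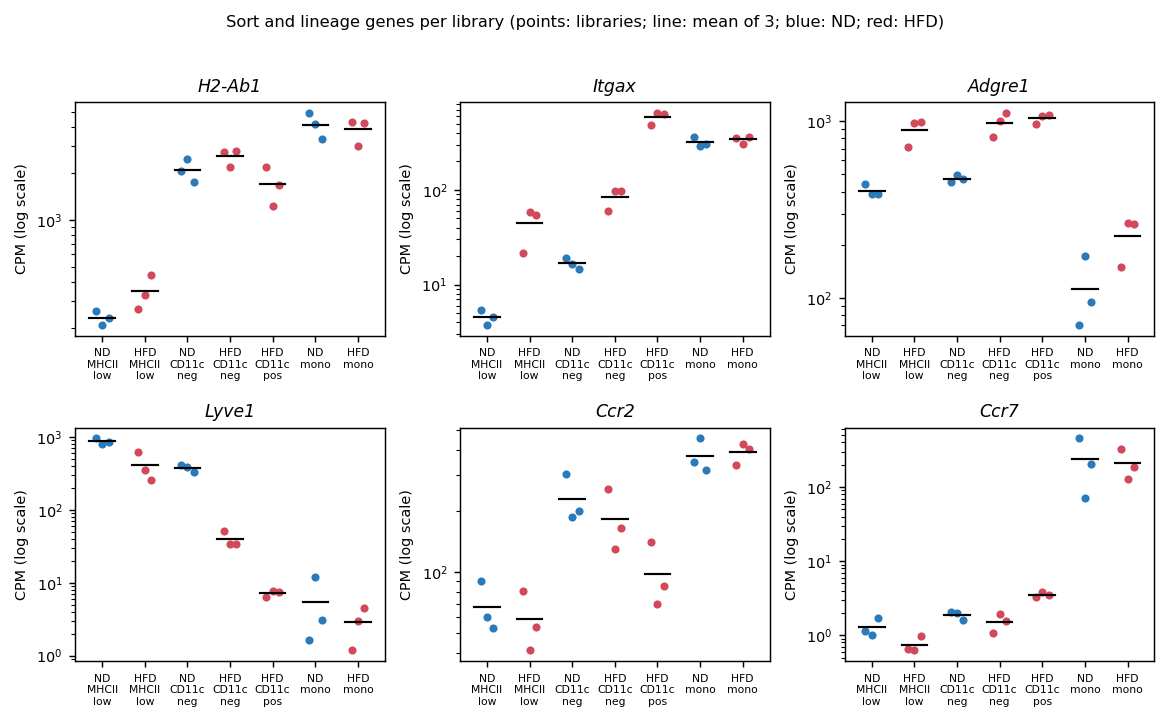
CPM (log scale) of sort and lineage genes in each library by group, with points for libraries and a line at the mean of 3. H2-Ab1 was lowest in the MHCII-low groups, with means of 233 CPM in lean and 346 CPM in obese mice, and Itgax was highest in CD11c-positive macrophages with a mean of 587 CPM.

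The diet comparison in MHCII-low macrophages asks which genes differ between obese and lean mice in this population. Gpnmb, a glycoprotein of lipid-laden macrophages (chromosome 6, 49036546 to 49070929 on GRCm38), rose from 15.7 ± 6.34 to 532 ± 235 CPM (SD, n = 3), a log2 change of 5.08 (SE 0.49, adjusted p = 2.62e-06). Trem2, a lipid-sensing receptor (chromosome 17, 48346401 to 48354147), rose from 36.5 ± 6.07 to 159 ± 38.2 CPM. The matrix protease Mmp9 (chromosome 2, 164940780 to 164955850) fell from 228 ± 39.4 to 9.72 ± 1.34 CPM, a log2 change of -4.55 (SE 0.47). Tpx2, a spindle protein of dividing cells, rose from 4.09 ± 0.559 to 20.1 ± 2.48 CPM.

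Of 20 lipid-associated macrophage genes 18 rose and 0 fell, with a median log2 change of 1.80 (adjusted p = 6.86e-21, and adjusted p = 0.0822 with an estimated correlation). Adjusted over the list alone the counts were the same. Atp6v0d2, a subunit of the proton pump, rose by a log2 change of 4.15 (SE 0.33) and the tetraspanin Cd9 by 3.47 (SE 0.34). Of 25 cell cycle genes 24 rose, also when adjusted over the list alone, with a median of 1.97 (adjusted p = 4.22e-46, and adjusted p = 0.000909 with an estimated correlation). Ccna2, a cyclin of S and G2 phase that a gene on the other strand overlaps, rose from 3.26 ± 0.841 to 16.8 ± 0.958 CPM. Per library total and without TMM scaling, summed cell cycle expression was 415 ± 44.5 CPM in lean and 930.3 ± 19.0 CPM in obese mice. Summed fibroblast markers stood at 1028 ± 118 and 1673 ± 788 CPM, with obese replicate 2 at 2580 and replicates 1 and 3 at 1159 and 1280 CPM.

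Among metabolic lists, 22 of 26 oxidative phosphorylation genes rose and 0 fell (23 adjusted over the list alone), with a median of 0.67 (adjusted p = 1.63e-10, and adjusted p = 0.255 with an estimated correlation). Of 19 fatty acid oxidation genes 17 rose and 1 fell, and 18 rose when adjusted over the list alone (adjusted p = 1.63e-10, and adjusted p = 0.0934 with an estimated correlation). Hadha, of mitochondrial beta oxidation, rose from 70.2 ± 4.16 to 143 ± 17.5 CPM. LXR targets and sterol efflux genes counted 6 higher and 1 lower of 10 (adjusted p = 2.28e-05, and adjusted p = 0.144 with an estimated correlation), with the same counts when adjusted over the list alone. The sterol exporter Abcg1 rose from 35.7 ± 4.82 to 208 ± 71.9 CPM. Of 24 lysosome genes 11 rose and 0 fell, or 13 and 2 adjusted over the list alone (adjusted p = 8.09e-06, and adjusted p = 0.330 with an estimated correlation). Cholesterol synthesis counted 9 higher and 2 lower of 20 by both adjustments (adjusted p = 0.00438, and adjusted p = 0.330 with an estimated correlation). Glycolysis, at 9 higher and 3 lower of 17 and 10 higher adjusted over the list alone, did not pass as a list (adjusted p = 0.0515).

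Resident macrophage genes counted 0 higher and 6 lower of 22 by both adjustments (adjusted p = 0.0421, and adjusted p = 0.504 with an estimated correlation). Timd4, a receptor for dying cells, fell from 89.7 ± 16.7 to 16.6 ± 5.91 CPM and Cd163, the haemoglobin scavenger receptor, from 1618 ± 81.2 to 760.1 ± 288 CPM. Lyve1, at 865 ± 80.5 in lean and 411 ± 195 CPM in obese mice, did not pass (adjusted p = 0.0878). Pla2g2d, a secreted phospholipase, fell from 109 ± 18.5 to 12.5 ± 4.62 CPM. Of 18 immediate early and dissociation genes 1 rose and 8 fell, or 10 adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.406 with an estimated correlation). Of 23 interferon response genes 0 rose and 4 fell, or 1 adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.406 with an estimated correlation). Their summed level, without TMM scaling, spread widely in lean libraries, from 676.9 to 1327 CPM, against 454.9 to 628.5 CPM in obese ones. Higher and lower counts were 4 and 1 of 11 for MHC class II, 1 and 4 of 22 for inflammatory response, 2 and 2 of 18 for chemokines, 8 and 3 of 24 for matrix remodelling and growth factors, and 3 and 5 of 18 for the monocyte list, none of which passed. Adjusted over the list alone these counts were 5 and 2, 1 and 4, 2 and 2, 8 and 4, and 4 and 5.

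Markers of other cell types also moved, as did signs of library quality. Genes detected at an equal depth of 11245851 counts ran from 29322 to 32741 in lean and 24218 to 24717 in obese MHCII-low macrophages, and silent receptor reads were 186 ± 46.7 and 42.8 ± 10.2 CPM. Adipocyte genes counted 1 higher and 10 lower of 14 by both adjustments (adjusted p = 2.28e-05, and adjusted p = 0.0822 with an estimated correlation), and Car3 fell from 28.4 ± 2.50 to 3.23 ± 0.274 CPM. Of 10 mesothelial genes 7 fell, or 9 adjusted over the list alone (adjusted p = 0.000489, and adjusted p = 0.365 with an estimated correlation). Of 15 T and NK cell genes 11 fell by both adjustments while Il7r rose (adjusted p = 0.000289, and adjusted p = 0.137 with an estimated correlation). Of 11 B cell genes 5 fell, or 6 adjusted over the list alone (adjusted p = 0.00609, and adjusted p = 0.330 with an estimated correlation). Dendritic cell genes counted 1 higher and 8 lower of 20 by both adjustments (adjusted p = 0.0120, and adjusted p = 0.365 with an estimated correlation), among them Irf4 at 261 ± 42.0 in lean and 105 ± 43.8 CPM in obese mice. The fibroblast and preadipocyte (3 higher, 1 lower of 16), endothelial (0, 1 of 14), neutrophil (0, 1 of 7), mast cell and eosinophil (2, 0 of 9) and erythroid (0, 1 of 6) lists did not pass. Adjusted over the list alone they counted 3 and 0, 0 and 0, 0 and 0, 1 and 0, and 0 and 3.

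In all 7030 of 22935 genes were called, 3864 higher and 3166 lower. Of the genes called with a mean of at least 10 CPM, 2792 were higher and 776 lower. Over all genes the balance turned with DESeq2 size factors (3122 higher, 3629 lower), DESeq2 (3540, 4248), no filter (3387, 3609), the compared libraries alone (3466, 3543) and without lean replicate 1 (2950, 2969). The number called was 3323 without obese replicate 2, 3566 without obese replicate 3, 4187 without lean replicate 2 and 4468 without lean replicate 3.

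**Figure D3:**
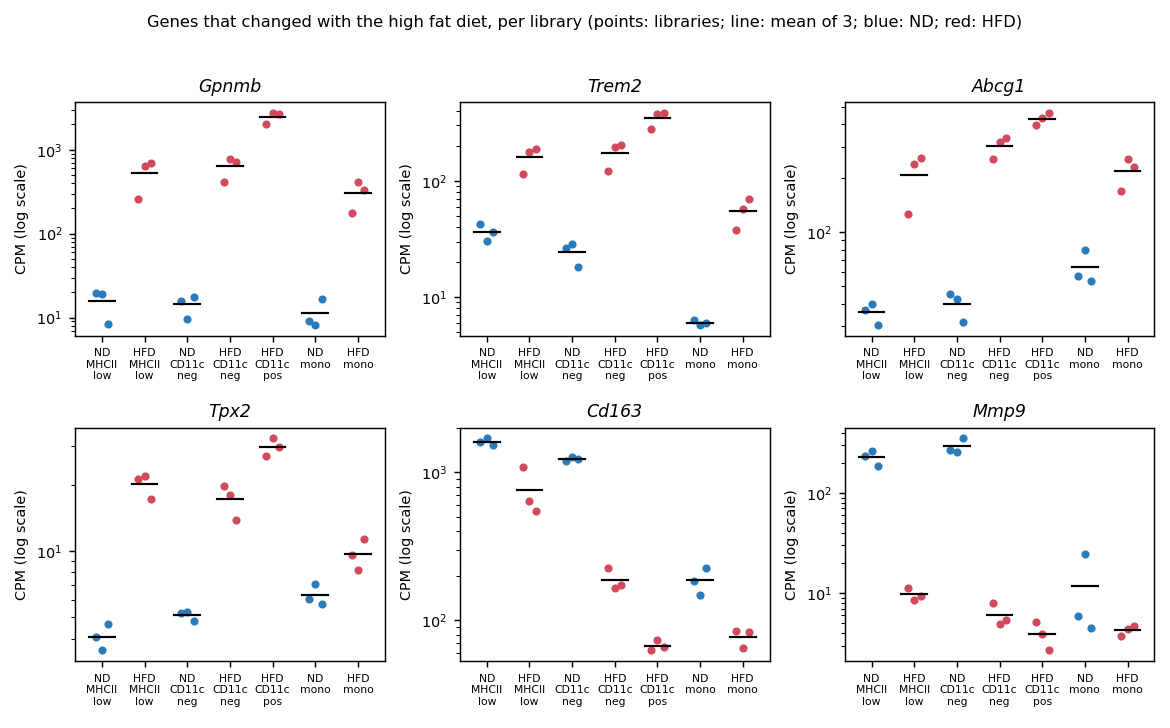
CPM (log scale) of genes named for the diet comparisons in each library by group, with points for libraries and a line at the mean of 3. Gpnmb had lean means of 11.3 to 15.7 CPM and obese means of 308 to 636 CPM in the populations with both diets.

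In CD11c-negative macrophages the same question was asked of the MHC class II positive cells without CD11c. Gpnmb rose from 14.4 ± 4.27 to 636 ± 195 CPM (SD, n = 3), a log2 change of 5.46 (SE 0.50, adjusted p = 1.53e-06), and Trem2 from 24.5 ± 5.48 to 172 ± 45.4 CPM. The largest rise was that of the myosin heavy chain gene Myh15 (chromosome 16, 49057486 to 49199104), from 0.230 ± 0.0441 to 65.6 ± 33.2 CPM. Mmp9 fell from 291 ± 51.2 to 6.08 ± 1.67 CPM, a log2 change of -5.58 (SE 0.49). Cd163 fell from 1232 ± 37.5 to 187 ± 32.5 CPM and Lyve1, a hyaluronan receptor of resident macrophages, from 372 ± 42.8 to 39.6 ± 10.4 CPM.

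Of 22 resident macrophage genes 0 rose and 14 fell, or 1 and 14 adjusted over the list alone, with a median of -1.18 (adjusted p = 1.90e-08, and adjusted p = 0.187 with an estimated correlation). Timd4 fell from 29.7 ± 2.47 to 1.73 ± 0.359 CPM. Lipid-associated macrophage genes counted 18 higher and 0 lower of 20 by both adjustments (adjusted p = 6.59e-23, and adjusted p = 0.0704 with an estimated correlation). Cell cycle genes counted 23 higher and 0 lower of 25, or 24 adjusted over the list alone, with a median of 1.36 (adjusted p = 3.24e-26, and adjusted p = 0.0143 with an estimated correlation). The replication factor Mcm6 rose from 24.5 ± 3.00 to 65.8 ± 1.79 CPM and the topoisomerase Top2a from 27.3 ± 6.97 to 79.7 ± 15.9 CPM. Without TMM scaling, summed cell cycle expression was 505 ± 63.9 CPM in lean and 940.4 ± 92.0 CPM in obese mice. Summed fibroblast markers were 966 ± 154 and 1781 ± 882 CPM, with obese replicate 2 at 2795 and replicates 1 and 3 at 1192 and 1357 CPM.

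LXR targets and sterol efflux counted 6 higher and 0 lower of 10, or 7 adjusted over the list alone (adjusted p = 1.59e-07, and adjusted p = 0.104 with an estimated correlation), with Abcg1 up from 39.8 ± 7.32 to 302 ± 42.2 CPM. Oxidative phosphorylation counted 22 higher of 26, or 24 adjusted over the list alone (adjusted p = 3.86e-11, and adjusted p = 0.220 with an estimated correlation). Fatty acid oxidation counted 16 higher and 1 lower of 19 by both adjustments (adjusted p = 8.55e-07, and adjusted p = 0.198 with an estimated correlation). Lysosome genes counted 11 higher and 2 lower of 24 by both adjustments (adjusted p = 4.17e-05, and adjusted p = 0.388 with an estimated correlation). Immediate early and dissociation genes counted 1 higher and 11 lower of 18 by both adjustments (adjusted p = 0.000129, and adjusted p = 0.304 with an estimated correlation), and the heat shock gene Hspa1b fell from 867 ± 473 to 88.5 ± 28.7 CPM. Of 23 interferon response genes 10 fell, or 11 adjusted over the list alone (adjusted p = 0.0170, and adjusted p = 0.466 with an estimated correlation). Their summed level, without TMM scaling, spread widely in lean libraries, from 488.7 to 1311 CPM, against 346.1 to 421.3 CPM in obese ones. Ccl2 and Ccl7, chemokines that attract monocytes, fell by log2 changes of -2.48 (SE 0.45) and -2.52 (SE 0.38), while the chemokine list, with 3 higher and 5 lower of 18, did not pass (adjusted p = 0.110).

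At that equal depth 26072 to 29265 genes were detected in lean and 24049 to 24278 in obese CD11c-negative macrophages, and silent receptor reads were 110.2 ± 35.4 and 30.2 ± 2.62 CPM. Adipocyte genes counted 1 higher and 8 lower of 14, or 10 lower adjusted over the list alone (adjusted p = 0.000195, and adjusted p = 0.114 with an estimated correlation). Dendritic cell genes counted 1 higher and 8 lower of 20, or 9 lower adjusted over the list alone (adjusted p = 0.00981, and adjusted p = 0.388 with an estimated correlation). T and NK cell genes counted 1 higher and 8 lower of 15, or 9 lower adjusted over the list alone (adjusted p = 0.0182, and adjusted p = 0.304 with an estimated correlation). The gene that rose was Il7r, the interleukin 7 receptor, at 11.7 ± 3.24 in lean and 106 ± 14.8 CPM in obese mice. The lists for cholesterol synthesis (9 higher, 3 lower of 20), glycolysis (9, 4 of 17), matrix remodelling and growth factors (8, 6 of 24), inflammatory response (0, 6 of 22), MHC class II (1, 0 of 11), monocyte (1, 2 of 18) and fibroblast (4, 0 of 16) did not pass. Neither did the endothelial (0, 0 of 14), mesothelial (0, 2 of 10), B cell (0, 2 of 11), neutrophil (0, 1 of 7), mast cell and eosinophil (2, 0 of 9) and erythroid (0, 3 of 6) lists.

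In all 7422 genes were called, 3842 higher and 3580 lower, or 2658 higher and 1220 lower among those of at least 10 CPM. Over all genes more were lower with DESeq2 size factors (3542 higher, 3847 lower) and with DESeq2 (3916, 4403). The number called was 4627 without obese replicate 2, 4493 without obese replicate 3 and 4650 without lean replicate 3.

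In monocyte-derived cells the diet comparison asks the same of cells that the labels trace to monocytes. Its p-values and SEs use a spread estimated over all 7 groups. They may be too small, because lean monocyte-derived libraries spread more widely than the others. Trem2 rose from 6.02 ± 0.275 to 54.9 ± 16.1 CPM (SD, n = 3), a log2 change of 3.19 (SE 0.27, adjusted p = 4.82e-07), and Gpnmb from 11.3 ± 4.59 to 308 ± 120 CPM. Hpgds, the haematopoietic prostaglandin D synthase, rose from 3.71 ± 0.209 to 34.0 ± 12.5 CPM. Arg1, arginase, fell from 29.0 ± 7.21 to 5.46 ± 1.93 CPM and Il1a, an alarmin cytokine, from 46.4 ± 22.2 to 9.45 ± 2.40 CPM. Itgax (log2 0.09, SE 0.26), Cd9 (0.42, SE 0.30), Mrc1 (-0.01, SE 0.15) and Ccr2 (0.05, SE 0.30) did not pass.

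Lipid-associated macrophage genes counted 17 higher and 0 lower of 20 by both adjustments, with a median of 1.81 (adjusted p = 2.12e-33, and adjusted p = 0.0288 with an estimated correlation). LXR targets and sterol efflux genes counted 7 higher and 0 lower of 10 by both adjustments (adjusted p = 9.24e-12, and adjusted p = 0.0288 with an estimated correlation). The nuclear receptor Nr1h3 rose from 4.93 ± 1.33 to 21.5 ± 4.01 CPM and Abcg1 from 63.6 ± 14.1 to 219 ± 43.5 CPM. Of 24 lysosome genes 19 rose and 0 fell, or 23 adjusted over the list alone (adjusted p = 1.06e-17, and adjusted p = 0.0894 with an estimated correlation), and the protease Ctsk rose from 2.98 ± 0.947 to 30.6 ± 11.2 CPM. Fatty acid oxidation counted 7 higher of 19, or 13 adjusted over the list alone (adjusted p = 7.41e-08, and adjusted p = 0.200 with an estimated correlation). Cell cycle genes counted 6 higher of 25 by both adjustments, with a median of 0.29 (adjusted p = 0.00491, and adjusted p = 0.690 with an estimated correlation). Without TMM scaling, summed cell cycle expression was 613 ± 44.5 CPM in lean and 728 ± 31.2 CPM in obese mice.

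In these cells 33372 to 35774 genes were detected in lean and 27431 to 32103 in obese libraries at equal depth, with silent receptor reads of 720 ± 431 and 120.2 ± 48.2 CPM. Fibroblast and preadipocyte genes counted 7 higher and 0 lower of 16, or 9 and 1 adjusted over the list alone, with a median of 1.29 (adjusted p = 0.000121, and adjusted p = 0.692 with an estimated correlation). Their summed level, without TMM scaling, was 351 ± 71.4 CPM in lean and 1103 ± 716 CPM in obese mice. The obese mean rests on replicate 2 at 1928 CPM, with replicates 1 and 3 at 729 and 652 CPM. Matrix remodelling and growth factors counted 7 higher and 3 lower of 24, or 8 and 3 adjusted over the list alone (adjusted p = 0.00422, and adjusted p = 0.650 with an estimated correlation). The summed level of this list, without TMM scaling, was not higher in obese mice. It was 11340 ± 7712 CPM in lean libraries, from 6234 to 20210, and 9835 ± 219 CPM in obese ones. Dendritic cell genes counted 1 higher and 4 lower of 20, or 6 lower adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.690 with an estimated correlation). Of 15 T and NK cell genes 3 fell (adjusted p = 0.0193, and adjusted p = 0.541 with an estimated correlation), and oxidative phosphorylation passed with 1 of 26 genes called (adjusted p = 0.00422, and adjusted p = 0.826 with an estimated correlation). No other list passed, among them resident macrophage genes with 4 higher and 3 lower of 22 and inflammatory response genes with 0 higher and 5 lower of 22. The chemokine list, not called, had a median of -0.06, a mean of 0.14 and a test direction of up.

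In all 3946 genes were called, 1707 higher and 2239 lower. More were higher among called genes of at least 10 CPM (1398 higher, 304 lower), without obese replicates 1 (2103, 855), 2 (2628, 1727) or 3 (1700, 535) and without lean replicate 3 (964, 743). The number called was 2235 without obese replicate 3, 9903 without lean replicate 2 and 1707 without lean replicate 3. It was 122 (97 higher, 25 lower) in a fit to the 6 compared libraries alone. Without both lean replicates 1 and 3 it was 847 (494, 353), a fit that leaves 1 lean library, assumed to vary like the other groups.

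Whether the diet effect differs between populations was tested as an interaction. Across 22935 genes, which are not independent replicates, the diet log2 changes of MHCII-low and CD11c-negative macrophages had Pearson's r = 0.815 and Spearman's rho = 0.844. Of the genes called in both, 3085 were higher in both (647 expected by chance) and 2059 lower in both (494 expected), and 0 had opposite signs. These expected numbers assume independent libraries, while obese libraries of equal number in different populations correlate (r = 0.128 to 0.732), so neither the overlap nor r measures a shared effect alone. With monocyte-derived cells the values were r = 0.650 and rho = 0.559 for MHCII-low macrophages, where 1816 of 1883 genes called in both had the same sign. For CD11c-negative macrophages they were r = 0.599 and rho = 0.531, with 1719 of 1816. The edgeR test of the difference between CD11c-negative and MHCII-low macrophages called 0 genes, while 634 had an unadjusted p under 0.05 and DESeq2 called 3. With no low-count filter the edgeR test called 123 genes. Without obese MHCII-low replicates 1 or 3 it called 2 and 1, and without obese CD11c-negative replicate 1 it called 1.

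**Figure D4:**
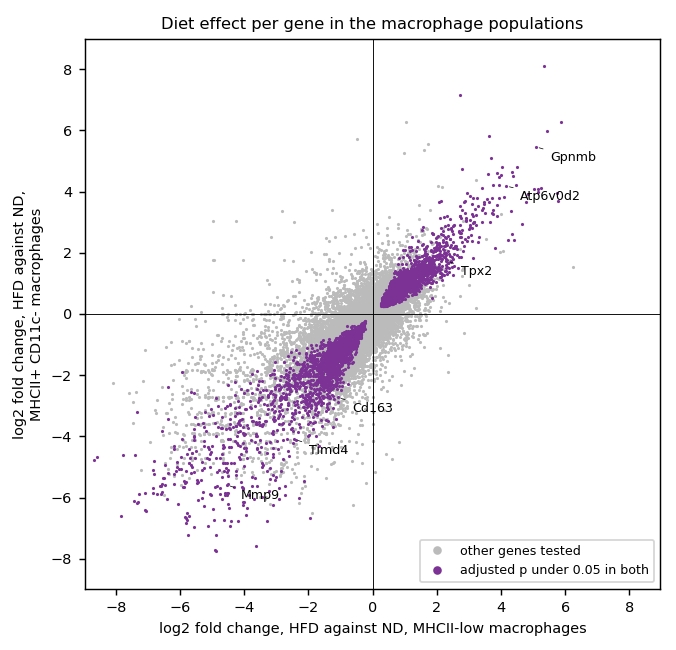
Log2 fold change of obese against lean for each of 22935 genes, in MHCII-low macrophages on the horizontal axis and CD11c-negative macrophages on the vertical axis, with genes called in both in purple. Genes called in both were 3085 higher and 2059 lower, with 0 of opposite sign.

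Against MHCII-low macrophages, the diet effect in monocyte-derived cells differed for 993 genes. With the wider spread of lean monocyte-derived libraries, p-values and SEs of both differences that involve these cells may be too small. The cell cycle list had 0 more positive and 19 more negative members of 25, with a median difference of -1.68 (adjusted p = 1.63e-40, and adjusted p = 0.00160 with an estimated correlation). Ccna2 stood at 8.51 ± 0.744 in lean and 8.60 ± 0.788 CPM in obese monocyte-derived cells, a difference of log2 effects of -2.34 (SE 0.26, adjusted p = 2.87e-05). The actin regulator Diaph3 differed by -2.001 (SE 0.18), Hpgds by 3.05 (SE 0.33) and the transcription factor Bhlhe41 by 2.36 (SE 0.23). Against this 993, the count was 603 and 566 without obese monocyte-derived replicates 2 and 3, and 2484 without lean monocyte-derived replicate 2. It was 415 and 482 without obese MHCII-low replicates 2 and 3, and 437 and 556 without lean MHCII-low replicates 2 and 3. With only the compared groups it was 315, with a block on the description number 1503, with no filter 1632 and with DESeq2 1829.

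Against CD11c-negative macrophages 1459 genes differed. The flagellin receptor Tlr5 (chromosome 1, 182954788 to 182976044) differed by 3.63 (SE 0.33, adjusted p = 5.98e-06) and the cytokine Il16 by 2.24 (SE 0.19). Cell cycle genes counted 0 more positive and 18 more negative of 25 (adjusted p = 1.22e-19, and adjusted p = 0.0421 with an estimated correlation), and resident macrophage genes 10 more positive and 0 more negative of 22 (adjusted p = 3.11e-14, and adjusted p = 0.103 with an estimated correlation). The count was 944 without obese monocyte-derived replicate 3, 3124 without lean monocyte-derived replicate 2, 955 and 718 without lean CD11c-negative replicates 1 and 3, and 829 and 940 without obese CD11c-negative replicates 2 and 3. It was 2833 with a block on the description number, and the counts with only the compared groups and with DESeq2 are given further below.

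**Figure D5:**
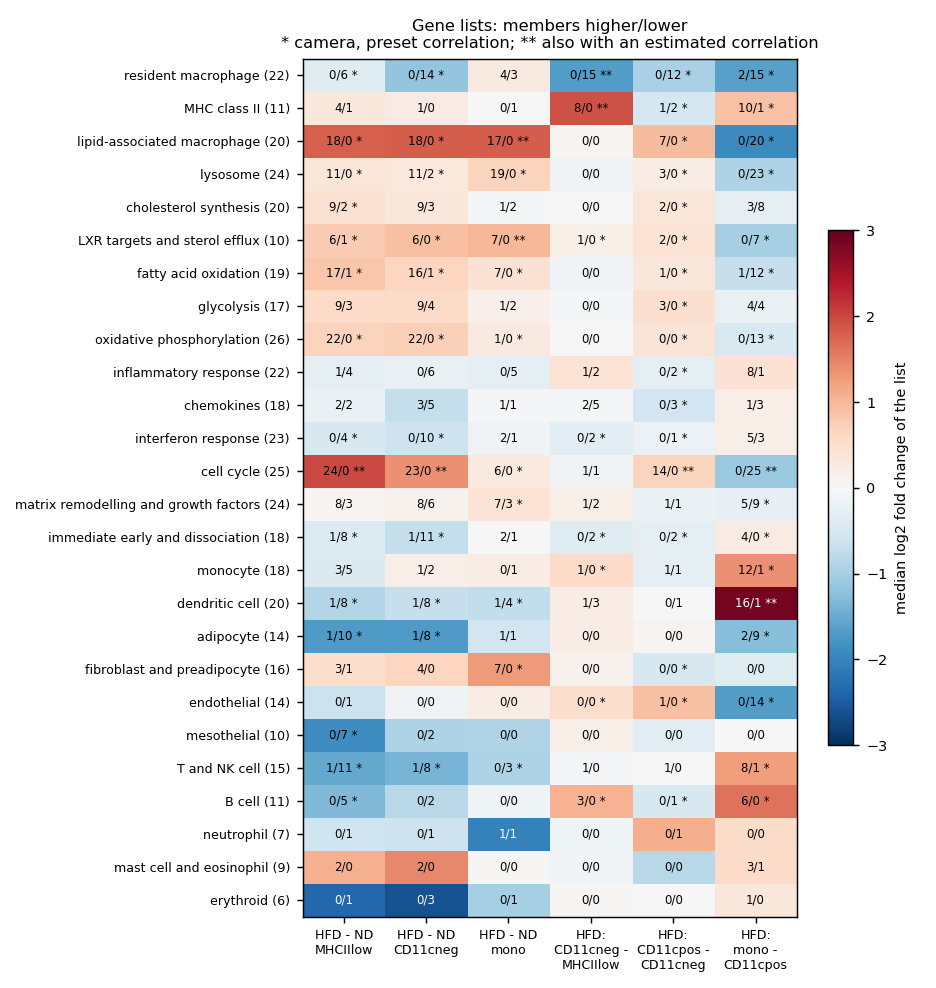
Heat map of the median log2 fold change of 26 gene lists in the 6 main comparisons, with the numbers of members higher and lower in each cell. A star marks lists with an adjusted p under 0.05 at the preset correlation and a pair of stars those that also passed with an estimated correlation, such as the cell cycle list in MHCII-low macrophages with 24 higher and 0 lower of 25.

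In obese mice CD11c-positive macrophages were compared with CD11c-negative ones to find what marks the CD11c-positive cells beyond the sort gene. F7, coagulation factor VII (chromosome 8, 13026034 to 13035809), stood at 63.7 ± 5.58 against 7.85 ± 0.613 CPM (SD, n = 3), a log2 difference of 3.02 (SE 0.37, adjusted p = 0.000252). Vsig8, an immunoglobulin domain gene overlapped on the other strand, stood at 90.5 ± 5.16 against 9.53 ± 3.76 CPM, and the macrophage elastase Mmp12, also overlapped, at 960.4 ± 280.2 against 138 ± 50.1 CPM. Tlr5 was lower, at 2.69 ± 0.317 against 13.9 ± 3.44 CPM, a log2 difference of -2.37 (SE 0.25). Cd163 was lower at 67.3 ± 5.32 against 187 ± 32.5 CPM.

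Of 20 lipid-associated macrophage genes 7 were higher and 0 lower, or 15 higher adjusted over the list alone, with a median of 0.95 (adjusted p = 1.90e-18, and adjusted p = 0.0752 with an estimated correlation). This list includes Itgax, the gene of the sort, so the sort itself sets part of the difference. The cathepsin Ctsl stood at 1259 ± 159 against 513 ± 96.7 CPM. Cell cycle genes counted 14 higher and 0 lower of 25, or 23 adjusted over the list alone (adjusted p = 2.44e-22, and adjusted p = 0.0238 with an estimated correlation). Resident macrophage genes counted 0 higher and 12 lower of 22, or 14 lower adjusted over the list alone (adjusted p = 1.65e-15, and adjusted p = 0.0752 with an estimated correlation). Cholesterol synthesis counted 2 higher of 20, or 8 adjusted over the list alone (adjusted p = 8.76e-07, and adjusted p = 0.0752 with an estimated correlation). Chemokines counted 0 higher and 3 lower of 18, or 1 and 7 adjusted over the list alone (adjusted p = 0.000154, and adjusted p = 0.316 with an estimated correlation), and glycolysis 3 higher of 17, or 9 adjusted over the list alone (adjusted p = 0.000331, and adjusted p = 0.324 with an estimated correlation).

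Oxidative phosphorylation (0 of 26 called; adjusted p = 3.99e-09, and adjusted p = 0.324 with an estimated correlation), fatty acid oxidation (1 of 19; 1.33e-05 and 0.316), lysosome (3 of 24; 0.000236 and 0.392) and LXR targets (2 of 10; 0.00389 and 0.324) were higher as lists. Endothelial markers were higher too (1 of 14; 2.79e-06, and adjusted p = 0.324 with an estimated correlation). Immediate early (2 of 18; 0.000544 and 0.329), inflammatory response (2 of 22; 0.00861 and 0.392), fibroblast (0 of 16; 0.0182 and 0.707), MHC class II (0.0260 and 0.480) and interferon response (1 of 23; 0.0260 and 0.480) were lower as lists. The B cell list was lower with 1 of 11 genes called (adjusted p = 0.0284), and had adjusted p = 0.392 with an estimated correlation and 0.0520 with a block on the description number. The mast cell and eosinophil list, not called, had a median of -0.83 and a test direction of up.

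In all 801 genes were called, 317 higher and 484 lower, and 2364 with a block on the description number. More were higher with DESeq2 (1209 higher, 950 lower), with the compared libraries alone (1646, 1526) and without CD11c-positive replicate 2 (41, 40). Without CD11c-negative replicates 1, 2 and 3 the count was 134, 337 and 199, and without CD11c-positive replicates 1, 2 and 3 it was 393, 81 and 134.

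CD11c-negative and MHCII-low macrophages of obese mice were compared to find genes that part them beyond MHC class II. Lyve1 stood at 39.6 ± 10.4 in CD11c-negative against 411 ± 195 CPM in MHCII-low macrophages (SD, n = 3), a log2 difference of -3.38 (SE 0.50, adjusted p = 0.000954). Timd4 was 1.73 ± 0.359 against 16.6 ± 5.91 CPM, and Fcna, a ficolin, 24.5 ± 2.30 against 257 ± 104 CPM. Ccr2, the receptor for Ccl2, was higher at 183 ± 65.2 against 58.4 ± 19.9 CPM, and the epithelial transcription factor gene Ehf (chromosome 2, 103263433 to 103303278) at 11.8 ± 2.36 against 0.977 ± 0.341 CPM. Trem2 (log2 0.12, SE 0.23) and Cd9 (0.38, SE 0.30) did not pass.

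Resident macrophage genes counted 0 higher and 15 lower of 22, or 18 lower adjusted over the list alone, with a median of -1.68 (adjusted p = 1.41e-32, and adjusted p = 0.00502 with an estimated correlation). MHC class II, the sort gene list, counted 8 higher of 11. Immediate early genes counted 0 higher and 2 lower of 18, or 7 lower adjusted over the list alone (adjusted p = 4.67e-06, and adjusted p = 0.273 with an estimated correlation), with Jun at 462 ± 29.8 against 850 ± 76.3 CPM. B cell genes counted 3 higher of 11, or 5 adjusted over the list alone (adjusted p = 5.40e-05, and adjusted p = 0.200 with an estimated correlation). The monocyte list passed with Ccr2 as its called gene (adjusted p = 0.00115, and adjusted p = 0.200 with an estimated correlation). Endothelial (0 of 14; 0.00597 and 0.925 with an estimated correlation) and LXR target lists (1 of 10; 0.0349 and 0.742) were higher, and interferon response (2 of 23; 0.00665 and 0.742) lower. Lipid-associated macrophage genes counted 0 of 20, or 2 higher adjusted over the list alone (adjusted p = 0.186), and adjusted p = 0.0459 with a block on the description number. Fatty acid oxidation also passed only with that block (adjusted p = 0.0514 without and 0.0383 with it).

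In all 699 genes were called, 274 higher and 425 lower, and 1332 with a block on the description number. The count was 235 without MHCII-low replicate 1, and 358, 363 and 338 without CD11c-negative replicates 1, 2 and 3. In lean mice 298 genes parted the same populations, 240 higher and 58 lower (438 with that block), of which 191 were also called in obese mice, all with the same sign. Alox15, a lipoxygenase of resident peritoneal macrophages, stood at 1.21 ± 0.533 in lean CD11c-negative against 23.1 ± 14.0 CPM in lean MHCII-low macrophages (SD, n = 3), and Prg4, lubricin, at 4.56 ± 1.61 against 52.7 ± 22.1 CPM. The lean count was 140, 181 and 135 without MHCII-low replicates 1, 2 and 3, and 177, 189 and 142 without CD11c-negative replicates 1, 2 and 3.

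Monocyte-derived cells of obese mice were compared with CD11c-positive macrophages, which also express Itgax. Ccr7, which guides dendritic cells to lymph nodes (chromosome 11, 99144196 to 99155077), stood at 215 ± 104 against 3.52 ± 0.302 CPM (SD, n = 3), a log2 difference of 5.93 (SE 0.56, adjusted p = 7.19e-07). Zbtb46, a transcription factor of conventional dendritic cells, stood at 60.6 ± 23.5 against 6.58 ± 0.140 CPM, and Il12b, a subunit of interleukin 12, at 15.5 ± 3.59 against 0.282 ± 0.139 CPM. Trem2 was lower at 54.9 ± 16.1 against 346 ± 58.2 CPM, and Adgre1, which encodes F4/80, at 225 ± 65.2 against 1039 ± 62.5 CPM. Ccr2 was higher at 387 ± 47.0 against 98.3 ± 36.9 CPM.

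All 20 lipid-associated macrophage genes were lower by both adjustments, with a median of -1.92 (adjusted p = 9.08e-18, and adjusted p = 0.0686 with an estimated correlation), and so were all 25 cell cycle genes (adjusted p = 2.18e-16, and adjusted p = 0.0463 with an estimated correlation). The lipid-associated list includes Itgax, on which CD11c-positive macrophages were sorted. Of 24 lysosome genes 23 were lower by both adjustments (adjusted p = 1.99e-14, and adjusted p = 0.0918 with an estimated correlation), among them the proton pump gene Atp6v1a at 195 ± 25.4 against 596 ± 10.2 CPM. Dendritic cell genes counted 16 higher and 1 lower of 20 by both adjustments, with a median of 2.87 (adjusted p = 4.19e-12, and adjusted p = 0.0463 with an estimated correlation). Monocyte genes counted 12 higher and 1 lower of 18 by both adjustments (adjusted p = 1.44e-05, and adjusted p = 0.0686 with an estimated correlation), with Plac8 at 12.6 ± 3.23 against 1.47 ± 0.241 CPM. Resident macrophage genes counted 2 higher and 15 lower of 22, or 16 lower adjusted over the list alone (adjusted p = 3.23e-06, and adjusted p = 0.226 with an estimated correlation). The exporter Abca1 of the LXR list was lower at 625 ± 137 against 1789 ± 177 CPM, with 0 higher and 7 lower of 10 in the list (adjusted p = 0.000162, and adjusted p = 0.226 with an estimated correlation).

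All 14 endothelial markers were lower (adjusted p = 1.33e-05, and adjusted p = 0.305 with an estimated correlation), Cldn5 at 4.42 ± 3.42 against 20.7 ± 5.42 CPM. T and NK cell genes counted 8 higher and 1 lower of 15 (adjusted p = 0.00980, and adjusted p = 0.236 with an estimated correlation) and B cell genes 6 higher of 11 (adjusted p = 0.00980, and adjusted p = 0.306 with an estimated correlation). Fatty acid oxidation (1 higher, 12 lower of 19; 4.07e-05 and 0.236 with an estimated correlation), oxidative phosphorylation (0, 13 of 26; 0.00117 and 0.524), matrix remodelling (5, 9 of 24; 0.00659 and 0.334) and adipocyte lists (2, 9 of 14; 0.0280 and 0.296) were lower. Immediate early genes were higher as a list (4 of 18; 0.0458, and adjusted p = 0.563 with an estimated correlation). Inflammatory response genes counted 8 higher and 1 lower of 22 (adjusted p = 0.0898, and 0.0255 with a block on the description number), and the fibroblast list passed, as lower, only with that block (adjusted p = 0.0376, 0.257 without it). The chemokine list, not called, had a median of 0.21, a mean of -0.02 and a test direction of down. In all 8884 genes were called.

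The remaining pairs of populations were compared in less detail. In obese mice 3284 genes parted CD11c-positive from MHCII-low macrophages (1352 higher, 1932 lower), with Lyve1 at 7.199 ± 0.667 against 411 ± 195 CPM (SD, n = 3) and F7 at 63.7 ± 5.58 against 5.33 ± 1.59 CPM. Resident macrophage genes counted 0 higher and 18 lower of 22 (adjusted p = 4.05e-39, and adjusted p = 0.00409 with an estimated correlation). That count of 3284 was 5076 with a block on the description number, 1139 without MHCII-low replicate 1, and 2066, 1598 and 1749 without CD11c-positive replicates 1, 2 and 3. Monocyte-derived cells of obese mice differed from MHCII-low macrophages in 7524 genes (3518 higher, 4006 lower), with Ccr7 at 215 ± 104 against 0.745 ± 0.194 CPM. Dendritic cell genes counted 16 higher and 2 lower of 20 (adjusted p = 1.67e-10, and adjusted p = 0.0351 with an estimated correlation). The chemokine and matrix lists were called as lower there (adjusted p = 0.0285 and 0.0408, with an estimated correlation 0.560 and 0.560), but not with a block on the description number (0.108 and 0.0840). From CD11c-negative macrophages monocyte-derived cells differed in 5461 genes, with Chp2, a calcineurin B homologue, at 1.52 ± 0.907 against 30.4 ± 1.54 CPM. That count was 3239 without monocyte-derived replicate 1, and 3359 and 3455 without CD11c-negative replicates 2 and 3.

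In lean mice monocyte-derived cells differed from MHCII-low macrophages in 10551 genes and from CD11c-negative macrophages in 10027. With the wider spread of lean monocyte-derived libraries, these p-values may be too small. Ccl22, a chemokine of dendritic cells, stood at 301 ± 262 CPM (SD, n = 3) against 0.639 ± 0.199 in MHCII-low and 2.01 ± 0.355 in CD11c-negative macrophages. Flt3, a growth factor receptor of dendritic cells, was 80.5 ± 51.6 against 0.538 ± 0.170 CPM in CD11c-negative macrophages. Lyve1 was 5.51 ± 5.52 against 865 ± 80.5 CPM in MHCII-low macrophages. Dendritic cell genes counted 13 higher and 2 lower of 20 against either population (adjusted p = 4.10e-06 and 5.20e-06, and adjusted p = 0.188 and 0.172 with an estimated correlation). Fibroblast markers counted 0 higher and 13 lower of 16 against either (adjusted p = 0.00299 and 0.00140, and adjusted p = 0.643 and 0.545 with an estimated correlation). A fit to the 6 compared libraries alone called 6421 and 5386 genes, and without both lean monocyte-derived replicates 1 and 3 which leaves 1 library assumed to vary like the other groups, the count against CD11c-negative macrophages was 6567.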

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

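The tests of other cell types and of fibroblasts as sources of cell cycle reads were chosen only after the result was seen. Values are given here where a test of the difference between 2 diet effects passed, by edgeR for genes and by camera at the preset correlation for lists. Between CD11c-negative and MHCII-low macrophages only lists passed in the main fit, and only at that correlation. Each is a difference of log2 effects, or for a list the median of its members.

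Between CD11c-negative and MHCII-low macrophages the edgeR test called 0 genes, with 634 at an unadjusted p under 0.05. DESeq2 called 3, and edgeR with no low-count filter called 123. In the main fit 12 lists passed at the preset correlation of camera. Their medians were -0.88 for resident macrophage, -0.49 for cell cycle, -0.27 for chemokine, -0.26 for immediate early, -0.18 for fatty acid oxidation and -0.0157 for matrix genes. They were 0.18 for LXR targets, 0.46 for B cell, 0.47 for endothelial, 0.48 for T and NK cell, 0.54 for monocyte and 0.68 for mesothelial genes. None of the 12 passed with an estimated correlation, where the smallest adjusted p was 0.0897 for the resident macrophage list. With a block on the description number, LXR target (adjusted p = 0.0889), T and NK cell (0.0642) and B cell genes (0.0586) also missed at the preset correlation.

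Between monocyte-derived cells and MHCII-low macrophages 993 genes were called. By smallest adjusted p they included Diaph3 at -2.001, Bhlhe41 at 2.36, Ccna2 at -2.34, Cenpe at -1.92 and Hpgds at 3.05. List medians were -1.68 for cell cycle, -0.44 for cholesterol synthesis, -0.44 for oxidative phosphorylation, 0.21 for lysosome, 0.41 for resident macrophage and 0.49 for monocyte genes. They were 0.62 for interferon response, 0.62 for immediate early, 0.81 for fibroblast, 0.84 for mesothelial, 0.87 for adipocyte and 1.08 for B cell genes. Of these 12 lists only cell cycle also passed with an estimated correlation (adjusted p = 0.00160), and lysosome (0.156) and monocyte genes (0.0622) missed with the description block.

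Between monocyte-derived cells and CD11c-negative macrophages 1459 genes were called. They included Tlr5 at 3.63, Hpgds at 3.25, Il16 at 2.24, Bhlhe41 at 2.23 and the nonmuscle myosin gene Myh10 at 1.41. List medians were -1.08 for cell cycle, -0.49 for oxidative phosphorylation, -0.42 for cholesterol synthesis, 0.21 for lysosome and 0.52 for interferon response genes. They were 0.76 for adipocyte, 0.85 for immediate early, 0.89 for chemokine and 1.54 for resident macrophage genes. Of these 9 lists only cell cycle also passed with an estimated correlation (adjusted p = 0.0421).

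Relabelling diet within the populations does not decide whether chance gave these counts. For CD11c-negative against MHCII-low macrophages the real labels called 0 genes, a count that 40 of 40 splits reach by definition, and the highest other split called 7378. For monocyte-derived cells against MHCII-low macrophages 5 of 40 splits reached 993, the real one included, with the highest other at 6617. Against CD11c-negative macrophages 6 of 40 reached 1459, with the highest other at 9562. The other splits that reached these counts, 4 and 5, all moved unequal numbers of libraries in the 2 populations. Such a split turns a diet effect that both populations share into a difference. The structure of the samples behind their high counts thus includes the diet itself, and chance is neither excluded nor shown.

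Cell cycle genes were higher with the high fat diet in both macrophage populations, and 1 library did not decide this, since at least 22 of 25 genes in MHCII-low and 21 of 25 in CD11c-negative macrophages were called higher without any 1 library. In MHCII-low macrophages the highest summed gain of 9 marker lists, in TMM-scaled CPM, was 26.7 CPM (mast cell and eosinophil) where cell cycle genes gained 535 CPM. In CD11c-negative macrophages it was 67.7 CPM (T and NK cell, 2 of 15 genes gaining) against 455 CPM. Mast cell and eosinophil genes gained in 7 of 9 in both, while every other list of the 9 had a negative median log2 change. How many cell cycle reads a cell brings per marker read was not measured, and no list covers other macrophages. More cells of another type in the obese sort thus stay open. More fibroblasts in the obese sort were tested by a slope. Over 12 obese libraries summed cell cycle expression changed by -0.00242 CPM for each CPM of fibroblast markers, where 0.782 and 0.537 would be needed. That slope rests on obese replicate 2 of each population, and libraries of equal number are not independent. Over the means of the 3 numbers the slope was 0.0177, with an upper 95% limit of 0.586 at 1 residual degree of freedom, which leaves the gains over all 3 libraries open. Without obese replicate 2 fibroblast markers gained 223 and 329.8 CPM and cell cycle genes 526 and 475 CPM. The slopes needed there, 2.36 and 1.44, and at least 1.76 and 1.23 without any 1 lean library, are more than 2 times that limit. That limit is itself set by replicate 2, and this split was made after the data were seen. It bears on replicates 1 and 3 only if cell cycle reads per fibroblast marker read are equal in all replicates, which was not tested. More fibroblasts in the obese sort thus stay open. A uniform background that differs between diets would have to be higher in obese libraries, but reads on silent receptors were lower there, at 0.00764 against 0.0317 CPM per kilobase in MHCII-low and 0.00548 against 0.0197 in CD11c-negative macrophages. The share of called cell cycle genes within it, 0%, follows from that direction and adds nothing. A difference in proliferation with the diet is a candidate explanation that no test here addressed.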

How the results depend on the processing

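Leaving out both lean monocyte-derived libraries 1 and 3 was chosen after seeing the data. All alternatives could be run. Of 705 results on named genes, DESeq2 size factors ended 6 calls and added 2, DESeq2 Wald tests (704 results) ended 3 and added 11, no filter ended 25 and added 17, only the compared groups ended 100 and added 10, and the block on title numbers ended 3 and added 6. The block on description numbers ended 1 call and added 11 over 428 results. Leaving out 1 library ended a call in 753 of 4782 runs, for 171 results, and added 10. Without both lean monocyte-derived libraries 65 calls ended and 3 were added over 217 results, and the log2 diet effects of Csf1r and Zbtb46 in monocyte-derived cells reversed to -0.00725 and 0.269. That fit leaves 1 lean library, assumed to vary like the other groups, so both reversals rest on lean replicate 2. Of 188 list calls 24 were kept with an estimated correlation, 130 with directional and 168 with mixed fry, 186 with DESeq2 size factors and 187 with the title block. The description block ended 10 of 151 list calls, beyond those in the report chemokine (adjusted p = 0.0759) and matrix genes (0.129) between lean monocyte-derived cells and MHCII-low macrophages, and among differences of diet effects LXR target (0.0889), T and NK cell (0.0642) and B cell genes (0.0586) for CD11c-negative and lysosome (0.156) and monocyte genes (0.0622) for monocyte-derived cells against MHCII-low macrophages. It added the gains that the report gives and changed no other list call that had passed.

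All 15 counts of called genes stayed within 1.5 times under DESeq2 size factors and under the title block. For diet the count ran from 3323 to 6281 without 1 library in MHCII-low macrophages, from 4493 to 6076 in CD11c-negative macrophages and from 1707 to 9903 in monocyte-derived cells, where it was 122 with only the compared groups and 847 without both lean libraries. For obese CD11c-positive against CD11c-negative macrophages it was 81 to 393 without 1 library, 1435 with no filter, 2159 with DESeq2, 2364 with the description block and 3172 with only the compared groups. For obese CD11c-negative against MHCII-low macrophages it was 235 to 505, 1215 with no filter, 1233 with DESeq2 and 1332 with the description block. For obese CD11c-positive against MHCII-low macrophages it was 1139 to 2685, 5076 with the description block and 5143 with only the compared groups. Obese monocyte-derived cells gave 6162 to 7373 against CD11c-positive, 5246 to 6509 against MHCII-low and 3239 to 4624 against CD11c-negative macrophages without 1 library.

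For lean CD11c-negative against MHCII-low macrophages the count was 135 to 189 without 1 library, 593 with DESeq2, 633 with no filter and 649 with only the compared groups. Lean monocyte-derived cells gave 8794 to 12866 against MHCII-low and 8766 to 12921 against CD11c-negative macrophages without 1 library, 6421 and 5386 with only the compared groups, and 6567 against CD11c-negative macrophages without both lean libraries. For the differences of diet effects, CD11c-negative against MHCII-low macrophages gave 0 to 2 without 1 library, 3 with DESeq2 and 123 with no filter. Monocyte-derived cells against MHCII-low macrophages gave 415 to 2484, 315 with only the compared groups, 1503 with the description block, 1632 with no filter and 1829 with DESeq2. Against CD11c-negative macrophages they gave 718 to 3124, 643 with only the compared groups, 2488 with DESeq2 and 2833 with the description block. The correlation of diet effects across genes was 0.926 for MHCII-low with CD11c-negative macrophages, 0.490 for MHCII-low macrophages with monocyte-derived cells and 0.528 for CD11c-negative macrophages with them among genes of at least 10 CPM. Among all tested genes, without 1 library, they ran from 0.646 to 0.800, from 0.572 to 0.652 and from 0.443 to 0.582. No filter tests 50228 genes and leaving out a library lowers the smallest group size of the filter, so other genes are tested, and the cause of the remaining changes was not tested. Of 22935 tested genes 8205 had a mean of at least 10 CPM, and how far counts per library limit the others was not tested.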

Other observations

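The families in the first paragraphs were put together only after the results were seen, so their p-values do not allow for that choice and establish no family effect. The tests of background and admixed cells were set before. Receptors for nucleic acids and lipoproteins of microbes were read as a family of 12 Toll-like receptors. Tlr13, a receptor for bacterial ribosomal RNA, was higher with the high fat diet by log2 2.00 (SE 0.22, n = 3) in MHCII-low macrophages, 1.90 (SE 0.22) in CD11c-negative macrophages and 1.80 (SE 0.23) in monocyte-derived cells. Tlr1 was higher by 1.29 and 1.08 in the macrophages, and Tlr7 by 1.53 (SE 0.22) in monocyte-derived cells. Tlr5 was lower (log2 -1.24, SE 0.22, and -2.06, SE 0.23) in the macrophages and higher by 1.57 (SE 0.24) in monocyte-derived cells. Members counted 3 higher and 3 lower in each macrophage population (adjusted p = 0.520 and 0.732) and 5 higher and 0 lower in monocyte-derived cells (adjusted p = 2.20e-06, and adjusted p = 0.0104 with an estimated correlation).

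Of 18 scavenger and apoptotic cell receptors, 5 were higher and 4 lower with the diet in MHCII-low macrophages (adjusted p = 0.520), 7 and 4 in CD11c-negative macrophages (adjusted p = 0.732), and 7 and 4 in monocyte-derived cells (adjusted p = 0.00340, and adjusted p = 0.0902 with an estimated correlation). Axl, a receptor for dying cells, was higher by 1.34, 1.47 and 1.63 (SE 0.20 in each), and the lipoprotein receptor Lrp1 by 1.31, 1.30 and 0.84. Of 16 eicosanoid enzymes and receptors, 1 was higher and 4 lower in MHCII-low macrophages, 1 and 4 in CD11c-negative macrophages and 1 and 5 in monocyte-derived cells, and the family passed in none of the 3 (adjusted p = 0.462, 0.0750 and 0.295). In CD11c-negative macrophages the leukotriene C4 synthase Ltc4s fell by 2.30 (SE 0.30), the cyclooxygenase Ptgs1 changed by -2.08 (SE 0.46) and the lipoxygenase Alox5 by -1.60 (SE 0.33).

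Genes lower with the high fat diet were set against a uniform background, because lean libraries held more reads on silent receptors. A loss of the size that background gives per kilobase of exon covered 3.81% of 2390 called genes under 10 CPM in MHCII-low macrophages. It covered 1.14% of 2360 in CD11c-negative macrophages and 3.67% of 1935 in monocyte-derived cells. With the background taken without 1 library of each diet, the share in monocyte-derived cells ran from 0.103% to 12.2%. For called genes of at least 10 CPM the share was 0% in each of the 3, which follows from the small size of that background beside median losses of 21.2, 23.4 and 22.1 CPM. Under 10 CPM it follows in large part too, since median losses were 1.04, 1.3 and 1.37 CPM. The background was highest in lean monocyte-derived cells, at 0.124 CPM per kilobase, so a called loss could hardly lie within it. The shares thus show only that a background of the size read on silent receptors is smaller than most of these losses. Silent receptors have many copies and their reads may be undercounted, so a larger background stays open. Other changes of cell composition or state with the diet stay open and were not tested.

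Dendritic cell genes were high in the monocyte-derived population, with Ccr7 at 215 ± 104 and Cd209a at 144 ± 48.2 CPM in obese mice (SD, n = 3). A share of admixed dendritic cells that varies between libraries is a candidate explanation. Over 6 libraries 17 list genes deviated from their group means together (median r = 0.650) and against 15 monocyte genes (median r = -0.357). Of 1000 random lists 95% lay under 0.561, but their median was 0.228, so other genes covary here too. The lean libraries also differed in quality, with 67.1% to 82.5% of counts on protein-coding genes, which this test does not separate. A uniform background covers 0% of the called genes, which follows from its small size beside a median gain of 46.7 CPM and adds nothing. Irf4, Irf8, Mgl2 and Clec10a are also known in macrophages, no gene of the list stands in another list, and the markers of the sort gate are not given in the sources used here. A state of monocyte-derived cells that varies between mice would look alike and was not tested.

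For each pair of groups the 6 libraries make 10 splits, too few for a share under 0.05. In 1 of 10 splits, the real one, the count was as large. The other splits mix the groups, which turns a real difference into spread within groups. Low counts in them therefore do not measure what chance gives. For diet the real counts were 7030 in MHCII-low macrophages, 7422 in CD11c-negative macrophages and 3946 in monocyte-derived cells, with the highest other split at 0, 0 and 751. In obese mice they were 801 for CD11c-positive against CD11c-negative, 699 for CD11c-negative against MHCII-low and 3284 for CD11c-positive against MHCII-low macrophages, with the highest other at 0 in each. Monocyte-derived cells gave 8884, 7524 and 5461 against CD11c-positive, MHCII-low and CD11c-negative macrophages of obese mice, with 0 in each. In obese mice, where libraries of equal number correlate, the 3 other splits that part every pair of equal number called 0. In lean mice the counts were 298, 10551 and 10027, with the highest other at 0, 0 and 328. The split with 751 set obese replicate 1 with lean replicates 1 and 3, the pair with the most reads on silent receptors.

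Col1a1, a fibroblast collagen, was highest within each obese population in replicate 2, at 463 CPM in MHCII-low, 461 CPM in CD11c-negative, 290.3 CPM in CD11c-positive macrophages and 368 CPM in monocyte-derived cells.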
